A study of Shewanella piezotolerans WP3 with 2 samples.

How the data were processed

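RNA was sequenced from Shewanella piezotolerans WP3 wild type and a fur mutant, grown without oxygen on 20 mM fumarate to the middle of the logarithmic phase. Per the labels' protocols, RNA of 3 harvests was mixed before the library was built, on an Illumina platform, so each genotype is 1 library and carries no replicate error. The aligner, the counting method, the strand setting and the genome build are not given in the sources used here.

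The authors deposited a table per library with an RPKM value per gene, named RPKM in the header of their combined table, with gene positions, strand and product names. Each has 2116 entries for 2113 genes, since 3 genes are listed 2 times with different mutant values; the first entry is used. A combined table holds 1160 genes, and its log2 ratio of wild type over mutant is, per the file headers, the authors' own. In the authors' deposited table this log2 ratio equals that of the deposited values for 447 of 1103 genes with values above 0 in both libraries and is offset by 0.305 for 654, each to within 0.001, and 2 follow neither. In the authors' deposited table the smallest absolute log2 ratio is 1.01. The authors' deposited p-value for each gene comes from a test that is not given in the sources used here; the median p-value in the authors' deposited table is 2.59e-15 and the largest is 0.475. With 1 library per genotype a p-value compares these libraries and not the genotypes, so the authors' deposited p-values were not used for any call.

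The depth was read from the values. Multiplied by coding length, 99.6% of the wild type values (all but 8) are whole multiples of 1 step to within 0.0005 reads, which gives the number of reads behind each value and a total of 2823772 reads. The mutant values give whole reads on such a step for 37.2% of entries, which are said to be on the common scale, and a total of 2456509 reads. Of the rest, 865 entries outside the authors' combined table are whole reads on a step 2.47 times smaller. Another 127, 157 and 155 entries, all in the combined table, give whole reads once their log2 ratio to the wild type is multiplied by 1.2, 1.25 or 1.75. Their step is 1.24 times smaller than that of the common scale, and the tolerance is 0.004 to 0.02 reads. This factor of 1.24 is the offset of 0.305 in the authors' log2 ratio. These divisors were found in the values, as those on a grid with a spacing of 0.05 at which over 20% of the tested entries are whole, a limit set after the values were seen. In all, 99.0% of mutant entries came out whole, and 2091 genes have recovered reads in both libraries; for the other 22, among them several metal-reducing, nitrate reductase and cytochrome c maturation genes, no reads were recovered and no interval is given. How the scales arose is not stated in the sources used here. The mutant total is read from the common scale. On the step 1.24 times smaller it would be 1.24 times larger. Mutant shares of reads and ratios of recovered reads would then be 1.24 times smaller. The entries with multiplied log2 ratios and the authors' offset log2 ratios go with the smaller step, and so with the larger total. Entries on the common scale go with the total used here. The values do not settle which total holds, and no interval here covers this. The value of 1 read lies between 0.0434 and 3.81 RPKM in the wild type library and between 0.0499 and 4.38 RPKM in the mutant library, depending on gene length, and 51 genes are listed at 0 in the former and 6 in the latter.

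The deposited RPKM values were compared as log2(value + 1) of mutant over wild type, a scale that understates ratios of genes with low values. A gene was called higher or lower when this log2 ratio was 1 or more, or -1 or less, and its larger RPKM was 10 or more. Ratios of recovered reads carry exact (Clopper-Pearson) 95% intervals conditional on the sum of both counts, shares of reads exact binomial intervals, single counts exact Poisson intervals, and a value of 0 a floor of 3 reads, which is less strict than the lower limit of the ratio interval. Gene lists were matched by gene symbol in the combined table or by product name, and a list with at least 3 measured members was placed by its median's percentile among 10000 random lists of the same size, matched on mean expression in 10 bins. These percentiles describe these 2 libraries. Random lists draw genes independently, while members of a list can lie side by side and be transcribed together. Percentiles of lists with such neighbours can therefore be too extreme. Runs are at least 3 neighbouring listed genes on 1 strand, at most 300 bases apart, that pass in 1 direction, and were set beside 1000 shuffles of the ratios over the genes. The limit of 300 bases was chosen with the data in hand. Members of a list that match only by accident of their name or, for the Tol genes, of their position were marked after the data were seen, and each list was also computed without them.

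The size rule, the 30 gene lists, the random lists, the runs and the naming rule were chosen before the data were examined. The naming rule takes fur, the 10 genes with the largest and the 10 with the smallest log2 ratio among those past the size rule with an annotated product, up to 4 members with the largest absolute log2 ratio of each described list, and the leading genes of the 3 longest runs. The lists cover siderophore synthesis, TonB-dependent receptors, energy transducers, heme uptake, inner membrane iron transport, iron storage, iron-sulfur clusters, oxidative stress, fumarate, nitrate, DMSO and TMAO, sulfur and metal reduction, cytochromes and their maturation, hydrogenases, oxidases, the tricarboxylic acid cycle, ATP synthase, NADH dehydrogenases, heme synthesis, flagellum, chemotaxis, ribosomal proteins, heat and cold shock, phage, transposases, fatty acids, and pili with secretion.

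Alternatives planned before the data were examined were TMM scaling (here an unweighted mean after trimming 30% of ratios and 5% of intensities), median-of-ratios scaling, pseudocounts of 0.5 and 10, no minimum, a minimum of 50 RPKM, a 4-fold threshold, the authors' log2 ratio, means in place of medians, and runs of at least 2 genes. Added after seeing the data were recovered reads scaled to gene length and library total, the same without the 3 most abundant genes, their median-of-ratios scaling, the counting interval wholly past 2-fold, other gaps between neighbours, lists without accidental matches, lists by product name alone, percentiles of lists among random lists on recovered reads, a wider match for importers, and growth genes outside clusters of ribosomal protein or ATP synthase genes. A planned search for Fur binding sites upstream of genes was not run, as no genome sequence was used here.

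The computation was tested on simulated data drawn from the real values, with 200 changed genes. The size rule found 92% of genes made 4-fold higher and 98% made 16-fold higher, 78% and 74% of genes made lower by these factors, and called 1.05% of unchanged genes. For this step the simulated libraries had 1 scale, no shift over all genes and counting noise only. These shares are therefore no error rates for the real libraries. Reads were recovered for 99.2% to 100% of genes on each simulated scale, 5% of random lists fell outside the middle 95%, and the ratio interval covered a true ratio in 96.4% of genes. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.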

Results

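Gene expression was measured by RNA sequencing in the deep-sea bacterium Shewanella piezotolerans WP3 and in a mutant of its fur gene, which encodes the ferric uptake regulator. Fur is a DNA-binding protein that carries ferrous iron and represses iron uptake genes when iron is plentiful. Both strains were grown without oxygen to the middle of the logarithmic phase on 20 mM fumarate, which the cells respire in place of oxygen. There was 1 library per genotype, made from RNA of 3 harvests that were mixed before the library was built. The deposited tables list 2113 genes, each counted once, with an RPKM value (reads scaled to gene length and library size) for each library. Of these genes, 2108 had a larger RPKM of 10 or more. Locus numbers run to at least swp_5163, so the tables may leave out many genes. Here and below, all genes means listed genes past this minimum, and medians and percentiles are relative to them. The size of 1 read in the values gives a total of 2823772 reads for the wild type library and 2456509 for the mutant library. Of these reads, the listed genes held 33.3% in the wild type library (exact binomial 95% interval 33.3 to 33.4) and 56.0% in the mutant library (55.9 to 56.1). The mutant total rests on the common scale of its values. On the step 1.24 times smaller the mutant share would be 1.24 times smaller, which the interval does not cover. The median listed gene had 65 reads in the wild type library and 228 in the mutant library.

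The comparison asks which genes differ when Fur is missing during respiration without oxygen. In the mutant library, genes of TonB-dependent uptake, a route by which iron enters the cell, stood above the other genes. These are the TonB-dependent receptors of the outer membrane (median log2 ratio 3.87, against 0.86 for all genes), and the TonB, ExbB and ExbD proteins that power them (4.16). Ribosomal protein (3.35) and ATP synthase genes (4.21) also stood above the other genes. Iron storage genes such as bacterioferritin (-1.43), fumarate reductase genes (-1.02), and genes listed as outer membrane cytochromes that pass electrons to metals (-1.31) were on balance lower in the mutant library. Each of these lists also lay outside the middle 95% of its random lists when recovered reads took the place of the deposited values. For the metal-reducing list this covers only the 3 of its 6 genes that have recovered reads. Several of these lists hold runs of neighbours, which the random lists do not, so their percentiles can be too extreme. The fixed name patterns matched too few importers of the inner membrane for a median, and 7 found by a wider match, made after the values were seen, lay inside the range of random lists (median 2.40, percentile 89.5). Importer genes whose product name gives no iron or heme can be missing from these 7.

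The fur gene itself (swp_2938, bases 3085224 to 3085655 on the plus strand, positions as the deposited tables give them) was listed at 381 RPKM in the wild type library, from 465 reads (exact Poisson 95% interval 424 to 509 reads). It was listed at 0 in the mutant library. Set against a floor of 3 reads for a count of 0, or 2.83 RPKM at that depth, fur was at least 135-fold lower in the mutant library. The lower limit of its exact 95% counting interval is 109-fold. These values match the genotype labels of both libraries.

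Across the 2108 genes, 984 were at least 2-fold higher in the mutant library, 129 were at least 2-fold lower and 995 were neither, on the log2 scale of RPKM plus 1. The call of neither depends on the scale of the mutant values. It takes in all 865 entries outside the combined table whose mutant values are 2.47 times smaller. From recovered reads their log2 ratios ran from 0.49 to 2.30, with a median of 1.76. Counts of higher and neither genes in the lists below rest on the same values. Of the genes past 2-fold, 88.4% were higher, against 61.6% after TMM scaling (666 higher, 416 lower), 65.7% after median-of-ratios scaling (691 and 361) and 53.2% after median-of-ratios scaling of the recovered reads (404 and 356). The median log2 ratio of all genes was 0.86 as deposited, -0.09 after TMM scaling, 0.02 after median-of-ratios scaling and 2.14 for recovered reads scaled to the library total. Lists outside the range of their random lists are therefore given with their distance from the median of all genes. With 1 library per genotype no replicate check of any difference is possible. Intervals and floors cover counting error only, since PCR copies cannot be told from separate molecules. They do not cover the choice of the mutant total, which could lower every ratio of recovered reads by a factor of 1.24, or 0.305 in log2. The mutant values follow several scales, and for 1205 genes the deposited ratio lies outside the counting interval of the recovered reads. Ratios of such genes are given without an interval or said to be off the common scale.

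**Figure D1:**
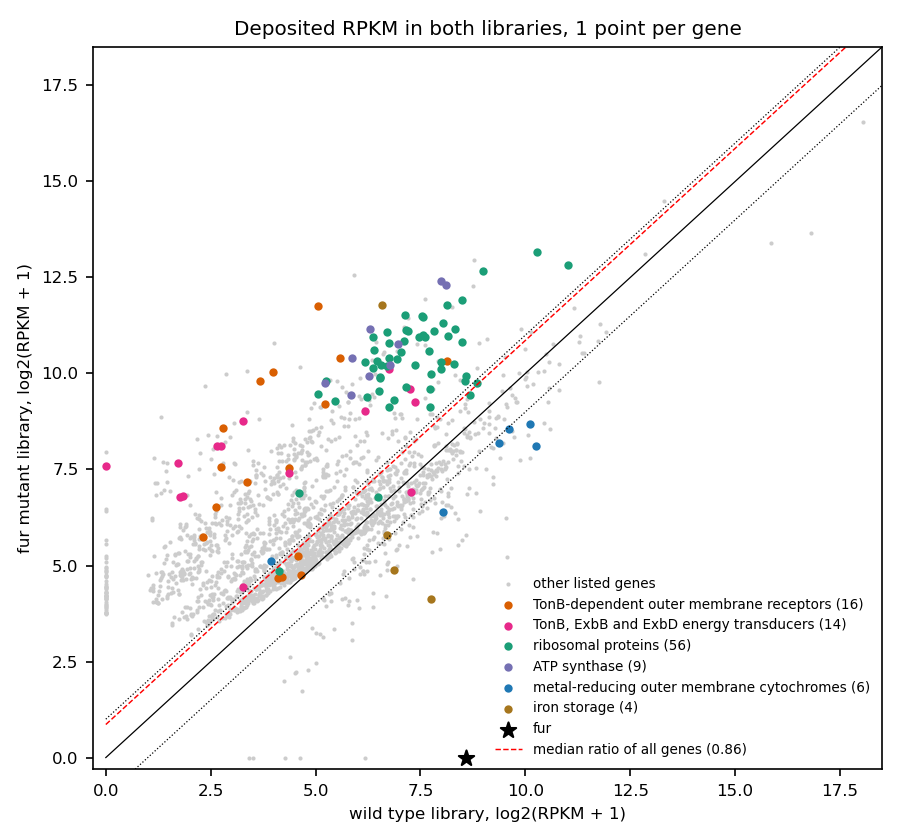
Each point is a gene, with log2 of (RPKM + 1) in the wild type library on the horizontal axis and in the fur mutant library on the vertical axis; the solid line marks equal values, the dotted lines 2-fold, and the dashed red line the median ratio of all genes, 0.86. TonB-dependent receptors, energy transducers, ribosomal proteins and ATP synthase lie mostly above the dashed line. Of 6 genes listed as metal-reducing cytochromes, 5, MtrB among them, lie below the lower dotted line, and fur is at 0 in the mutant library. The list medians kept these directions under the 5 other scalings, of which the 3 on recovered reads cover 3 of these 6 genes.

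Among genes with an annotated product, those with the largest log2 ratios were led by a TonB gene, swp_3979 (4195146 to 4195889, plus strand). It was listed at 0 in the wild type library and at 192 RPKM in the mutant library, where it had 350 reads. Against a floor of 3 reads it was at least 134-fold higher there, and the lower limit of its counting interval is 108-fold. Asparagine synthetase B, swp_1809 (1852162 to 1853826, minus strand), makes asparagine from aspartate. It had 1.49 RPKM in the wild type and 467 RPKM in the mutant library, a ratio with an exact 95% counting interval of 152 to 782. A pair of cytochrome c genes close together on the plus strand followed, swp_4579 (4798747 to 4800144; 6.33 and 1022 RPKM, interval 109 to 250) and swp_4577 (4796489 to 4796815; 15.2 and 1774 RPKM, interval 69.5 to 215). The hemoglobin receptor swp_3978 (4192789 to 4194840, minus strand) had 32.1 RPKM in the wild type and 3467 RPKM in the mutant library, and its interval was 93.5 to 125. The other members of these 10 were a putative zinc protease, swp_4956 (log2 ratio 6.64), a blue copper protein, swp_1892 (6.33, from 2 wild type reads, with an interval of 36.0 to 1093), and a SAM-dependent methyltransferase, swp_3805 (6.20). A TonB-dependent receptor, swp_4592 (6.14), and the ATP-binding subunit of the hemin importer, swp_3984 (6.13), completed them.

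After fur, the genes with the smallest ratios were led by the transmembrane subunit of fumarate reductase, swp_0429 (446026 to 446703, plus strand). It was listed at 756 RPKM in the wild type and 36.6 RPKM in the mutant library, 16- to 27.1-fold lower by its counting interval. Bacterioferritin swp_1175 (1177916 to 1178383, plus strand) had 213 and 16.5 RPKM and was 8.12- to 21.8-fold lower. The universal stress protein UspA, swp_4459 (4676169 to 4677047, minus strand), had 739 and 74.6 RPKM, 8.44- to 11.7-fold lower. A sigma factor of the extracytoplasmic function family, swp_3860 (4070857 to 4071390, plus strand), which directs RNA polymerase to its own set of promoters, had 359 and 49.6 RPKM and was 5.6- to 9.53-fold lower. The remaining genes of these 10 were an acetyltransferase, swp_0118 (log2 ratio -2.81), a redox protein annotated as a regulator of disulfide bonds, swp_4320 (-2.56, from 4 mutant reads), a LysR-family regulator, swp_1349 (-2.54), another transcriptional regulator, swp_3898 (-2.50), and an ATPase-like protein, swp_4353 (-2.45). All 20 genes of both groups, fur among them, have mutant values on the common scale, and 0 of them turned sign under any scaling.

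The TonB-dependent receptors of the outer membrane were higher as a group: of 16 measured, 12 were higher, 0 lower and 4 neither. They were matched by name, which for members such as swp_4592 gives no substrate. Their median log2 ratio was 3.87, 3.01 above that of all genes, at percentile 100 among 10000 random lists matched on expression. On recovered reads it was 1.73 above all genes, also at percentile 100. Besides swp_3978 and swp_4592, the largest ratios belonged to swp_1134 (1137993 to 1140149, minus strand; 14.9 and 1043 RPKM, interval 56.7 to 86.8) and swp_3303 (3484350 to 3486422, plus strand; 5.98 and 384 RPKM, interval 46.0 to 92.5). The energy transducers, which couple the receptors to the proton gradient, included 14 measured genes, 13 of them higher and 1 neither. Of these, swp_1828 and swp_1829 lie beside TolA and TolB and are marked as accidental matches to the Tol system; without them 11 of 12 were higher and the median was the same, at percentile 100. Their median was 4.16, 3.30 above all genes and at percentile 100, and on recovered reads 2.03 above all genes, also at percentile 100. Next to swp_3979 stood the proton channel gene swp_3980 (4196083 to 4196850, plus strand; 2.31 and 201 RPKM, interval 37.1 to 271). The ExbD gene swp_4950 (5176452 to 5176859, minus strand) had 8.68 and 433 RPKM, and its neighbour swp_4952, another biopolymer transport gene, had 5.25 and 276 RPKM. These neighbours overlap, so reads in the shared bases cannot be assigned to either.

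The fixed name patterns found few inner membrane importers. The hemin importer subunit swp_3984 (4199357 to 4200163, plus strand) was the single gene of the heme uptake list and had 3.51 and 315 RPKM, with an interval of 45.3 to 209. The list of iron transport across the inner membrane held 2 genes, named here after their values were seen: the ferrichrome transporter subunit FhuC, swp_2099, with 3.69 and 60.4 RPKM (interval 8.04 to 38.9), and the ferrous iron permease FeoB, swp_3270, with 240 and 1276 RPKM (interval 5.03 to 5.61). The log2 ratio of FeoB, 2.40, is above the median of all genes on recovered reads, 2.14, by less than it is above that of the deposited values, 0.86. A wider name match, made after the values were seen, found 7 listed iron and heme importer genes, all 7 higher. Their median was 2.40, at percentile 89.5, and at percentile 82.8 on recovered reads, so these 7 lay inside the range of random lists. A name match can miss importer genes whose product name gives no iron or heme. A periplasmic binding protein, swp_3982, and a permease, swp_3983, lie beside swp_3984 in a run with log2 ratios of 3.60 or more. A solute-binding protein, swp_4107, and a permease, swp_4106, lie beside the Fe(3+) ATPase swp_4105 in a run with ratios of 1.36 to 4.37. Both runs were singled out after their values were seen. Among the 7 genes, FeoA, swp_3271, is listed 2 times and has a log2 ratio of 1.92 by its first entry and 0.62 by its second. Its entries have equal wild type values, and their mutant values differ by the factor of 2.47 between scales. The list of siderophore synthesis matched 0 of the listed genes by its fixed pattern, although 1 listed gene, swp_0085, is annotated as a vibrioferrin biosynthesis protein.

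**Figure D2:**
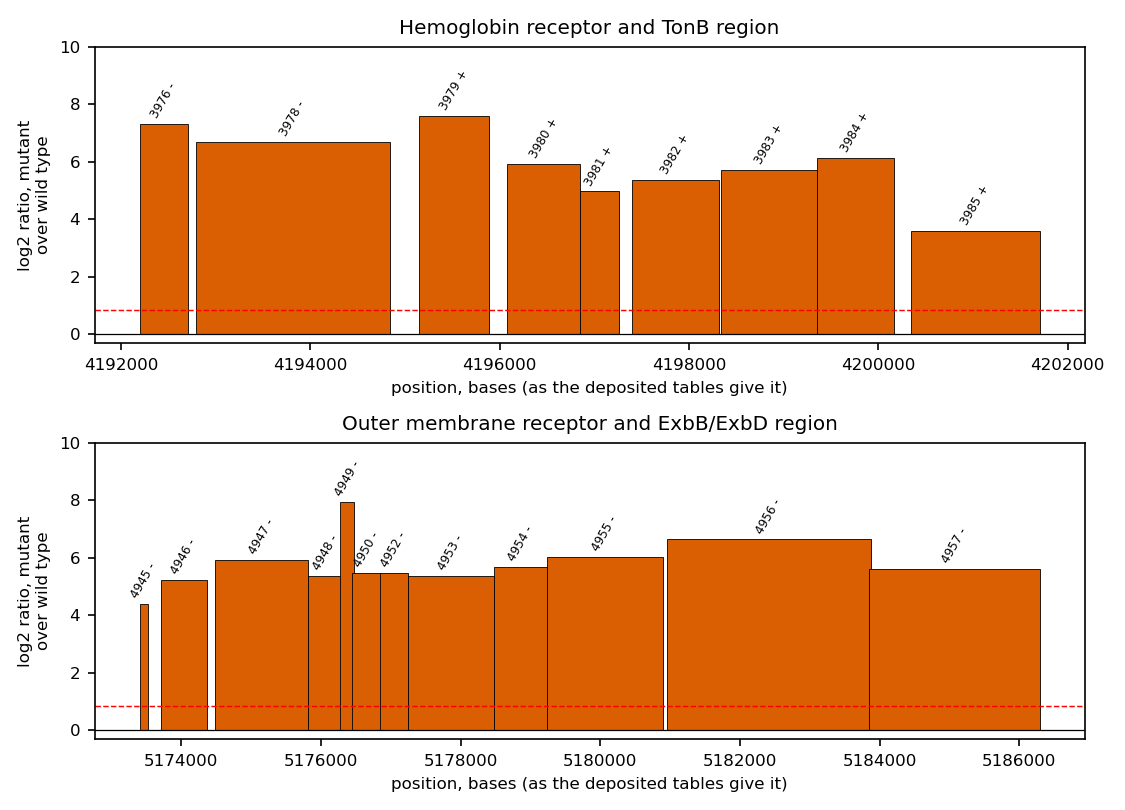
Bars span genes at their positions in bases (locus numbers with strand above each bar), and their height is the log2 ratio of mutant over wild type RPKM plus 1, with the dashed red line at the median of all genes, 0.86. In the region of the hemoglobin receptor swp_3978 and TonB swp_3979, and in that of the outer membrane receptor swp_4957 and ExbD swp_4950, each drawn bar is above that line; both regions were chosen after their values were seen.

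Iron storage genes went the other way, apart from bacterioferritin-associated ferredoxin, which helps to release stored iron. Of 4 measured genes 1 was higher, 2 lower and 1 neither, and the median of -1.43 was -2.29 from that of all genes, at percentile 0.11. On recovered reads it was -3.57 from all genes, at percentile 0.05; the mean of the deposited ratios was -0.31. The ferredoxin swp_0771 (772264 to 772455, minus strand) was listed at 94.1 RPKM in the wild type and 3528 RPKM in the mutant library, an interval of 28.4- to 50.6-fold higher. The second bacterioferritin gene, swp_1176, next to swp_1175, had 115 and 28.7 RPKM (2.74- to 6.03-fold lower), and the ferritin and Dps gene swp_0167, which did not pass 2-fold, had 103 and 54.7 RPKM.

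The iron-sulfur cluster list had 5 measured genes, of which 3 were higher, 1 lower and 1 neither, with a median of 1.31 at percentile 73.6. Of its members, 3 match by name only as iron-sulfur binding proteins, which leaves 2 assembly genes, too few to place as a group. The binding proteins were swp_1812 (2.51 and 112 RPKM, interval 28.6 to 73.3), swp_3636 (457 and 1135 RPKM, off the common scale) and swp_5134 (254 and 122 RPKM, 1.86- to 2.36-fold lower). The co-chaperone HscB, swp_1698, had 9.44 and 41.2 RPKM, also off the common scale. Heme and tetrapyrrole synthesis genes lay inside the range of random lists: of 11, 3 were higher, 3 lower and 5 neither. Their median of 0.29 at percentile 16.8 turned sign under the 3 scalings that bring the median of all genes near 0. These are TMM and median-of-ratios scaling of the values and median-of-ratios scaling of the recovered reads, called the centring scalings from here on. TMM and median-of-ratios scaling of the values lower each log2 ratio by up to 0.99 and 0.87, so medians between 0 and about these sizes turn by construction. A turned sign therefore shows where 0 lies and is no test of a list. The higher genes were the coproporphyrinogen III oxidase swp_3985 (28.9 and 360 RPKM), glutamate-1-semialdehyde aminotransferase swp_1129 (27.7 and 317 RPKM) and the oxygen-independent coproporphyrinogen oxidase swp_3679 (3.43 and 35.8 RPKM). Lower were the protoporphyrinogen oxidase swp_0051 (450 and 118 RPKM) and, named after their values were seen, another gene of that name, swp_4046 (596 and 157 RPKM), and delta-aminolevulinic acid dehydratase swp_0440 (602 and 267 RPKM).

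Oxidative stress defence genes also lay inside the range of random lists: of 18 measured, 7 were higher, 1 lower and 10 neither. Their median was 0.71 at percentile 44.0, and its sign turned under the 3 centring scalings. The nickel superoxide dismutase swp_3819, which removes superoxide, had 33.7 RPKM in the wild type and 558 RPKM in the mutant library (interval 12.3 to 22.7). The peroxide-removing alkyl hydroperoxide reductase genes swp_2738 (7.57 and 124 RPKM) and swp_1821 (77.1 and 576 RPKM) were higher too. The thioredoxin-like gene swp_1734, the lower one, was named after its values were seen and had 405 and 129 RPKM. Of the list's 18 genes, 5 match by accident of their name, RecC (swp_2767, log2 ratio 3.07) among them, and without these 4 of 13 were higher, with a median of 0.34 at percentile 46.2.

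Genes for respiration with fumarate were lower on balance. Of 5 measured, 3 were lower, 1 higher and 1 neither, and the median of -1.02 was -1.88 from that of all genes, at percentile 0.28. On recovered reads it was -3.16 from all genes, at percentile 0.105. The neighbours of swp_0429, the flavoprotein subunit swp_0430 and the iron-sulfur subunit swp_0431, had 75.9 and 33.0 RPKM and 46.6 and 22.4 RPKM, or 1.91- to 2.77-fold and 1.43- to 3.07-fold lower. A flavocytochrome c gene with an export signal, swp_0220 (237962 to 239413, plus strand), had 7.32 and 121 RPKM and was 11.4- to 24.7-fold higher. The most abundant member, the flavocytochrome c gene swp_4352, was named after its values were seen and had 3869 RPKM in the wild type and 2146 RPKM in the mutant library, 1.76- to 1.85-fold lower.

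The list of outer membrane cytochromes that pass electrons to metals had 6 measured genes, 5 lower and 1 higher. Of these, MtrB is annotated as an outer membrane protein and not as a cytochrome. The median of the list, -1.31, was -2.17 from that of all genes, at percentile 0.09. TMM and median-of-ratios scaling of the values kept its sign over all 6 genes. For the 3 of them with recovered reads the median was -3.20 from all genes, at percentile 0.91. The decaheme cytochrome gene swp_3278 (3447753 to 3449792, plus strand) had 1210 and 276 RPKM, its neighbour swp_3277 had 1096 and 407 RPKM, and the MtrB gene swp_3280 had 660 and 289 RPKM. Their mutant values correspond to no whole reads, so no interval is given. Elsewhere, the decaheme gene swp_0896 (896402 to 898747, plus strand) had 264 and 83.1 RPKM, 2.87- to 3.52-fold lower. Named after their values were seen, MtrA, swp_3279, had 785 and 375 RPKM (1.94- to 2.26-fold lower), and swp_2374, which the combined table calls mtrF and the per-sample tables a rhomboid-like protein, had 14.4 and 33.8 RPKM. The 3 genes with recovered reads are swp_0896, MtrA and swp_2374, so their median is the value of MtrA alone. Without swp_2374, whose name is in doubt, too few would be left to place as a group.

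Nitrate and nitrite reduction split between gene clusters: of 11 measured genes 4 were higher, 4 lower and 3 neither. The median was 0.46 at percentile 32.8, and its sign turned under the 3 centring scalings. Without 2 accidental matches, 3 of 9 were higher and 4 lower, with a median of -0.27, -1.13 from all genes and at percentile 1.52, below the range of random lists. On recovered reads, which 6 of these have, it was inside that range, at percentile 6.88. The name pattern leaves out swp_2773 and swp_2772, annotated as nitrate/TMAO reductase subunits, with log2 ratios of 2.09 and 1.23. They lie in the same higher run as swp_2774 and swp_2775 below and were counted under DMSO and TMAO. The median with them was not computed, so the place below the range depends on the name match. The nitrate reductase catalytic subunit swp_2774 (2910979 to 2913468, minus strand) had 9.10 and 56.9 RPKM, 4.78- to 8.29-fold higher, and the adjacent periplasmic nitrate reductase gene swp_2775 had 21.3 and 119 RPKM. The other higher genes were the cytochrome c552 nitrite reductase swp_0613 (9.08 and 45.1 RPKM) and swp_1240, a polysulfide reductase subunit that matches by name. On recovered reads the log2 ratios of swp_2774, 2.52, and swp_0613, 2.19, are little above the median of all genes, 2.14. The lower genes, named after their values were seen, were another cluster of nitrate reductase genes, NapD swp_4456 (1392 and 419 RPKM), the catalytic subunit swp_4457 (225 and 107 RPKM) and NapB swp_4458 (102 and 31.6 RPKM), and the NapC/NirT cytochrome swp_4806 (1798 and 758 RPKM).

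The broad list of c-type cytochromes, with 31 measured genes, had 12 higher, 8 lower and 11 neither. Its median was 0.27 at percentile 5.54, and the sign turned under the 3 centring scalings. Without 9 accidental matches, 9 of 22 were higher and 8 lower, with a median of 0.58 at percentile 37.0. The list's largest ratios were those of swp_4579 and swp_4577, followed by a cytochrome c oxidase subunit III, swp_1425, listed at 0 in the wild type library, and a tetraheme cytochrome, swp_0221, next to swp_0220, with 17.0 and 273 RPKM. Against a floor of 3 reads, swp_1425, an accidental match, was at least 12.6-fold higher in the mutant library, with a lower limit of 9.72-fold for its counting interval. Of 8 cytochrome c maturation genes, 1 was higher and 7 neither, with a median of -0.18 at percentile 6.11, and of 1.42 for the 4 with recovered reads. Of 18 matches to hydrogenases and formate dehydrogenases, 7 were higher, 2 lower and 9 neither, with a median of 0.47 at percentile 43.1 whose sign turned under the 3 centring scalings. Without 7 accidental matches, 2 were higher, the formate dehydrogenase alpha subunit swp_4312 (11 and 179 RPKM, interval 13.6 to 19.6) and the maturation protein HypF, swp_2644 (24.2 and 118 RPKM, off the common scale). Then 2 were lower, the accessory genes HypC, swp_2646 (318 and 81.1 RPKM), and HypB, swp_2645 (297 and 90.3 RPKM). The median of these 11 was -0.30 at percentile 2.75, close to the lower edge of the range, and on recovered reads it was -1.14 from all genes at percentile 3.48. HypF, HypC and HypB were named after their values were seen.

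Genes of ATP synthase and of ribosomal proteins stood with the TonB-dependent receptors and energy transducers. All 9 measured ATP synthase genes were higher, with a median of 4.21, 3.35 above all genes and at percentile 99.99, and 2.07 above them at percentile 100 on recovered reads. They form 1 run of neighbours, from swp_5163 to swp_5155, so they are not 9 separate observations and these percentiles can be too extreme. All 9 mutant values were on the common scale. The subunit B gene swp_5160 (5389571 to 5390041, minus strand) had 77.4 and 2280 RPKM (interval 24.2 to 36.2), and subunit beta, swp_5156 (5385144 to 5386520), had 254 and 5387 RPKM (interval 19.9 to 22.7). Subunits delta, swp_5159, and gamma, swp_5157, had log2 ratios of 4.53 and 4.52. Of 56 ribosomal protein genes 52 were higher, 0 lower and 4 neither, with a median of 3.35, 2.49 above all genes and at percentile 100. On recovered reads it was 1.21 above them, also at percentile 100. The genes of proteins L13, swp_0701 (81.2 and 1985 RPKM, interval 20.0 to 30.2), and S15, swp_1221 (36.7 and 893 RPKM, interval 16.6 to 36.9), led the list, with S7, swp_2006 (log2 ratio 4.42), and S21, swp_1114 (4.39).

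**Figure D3:**
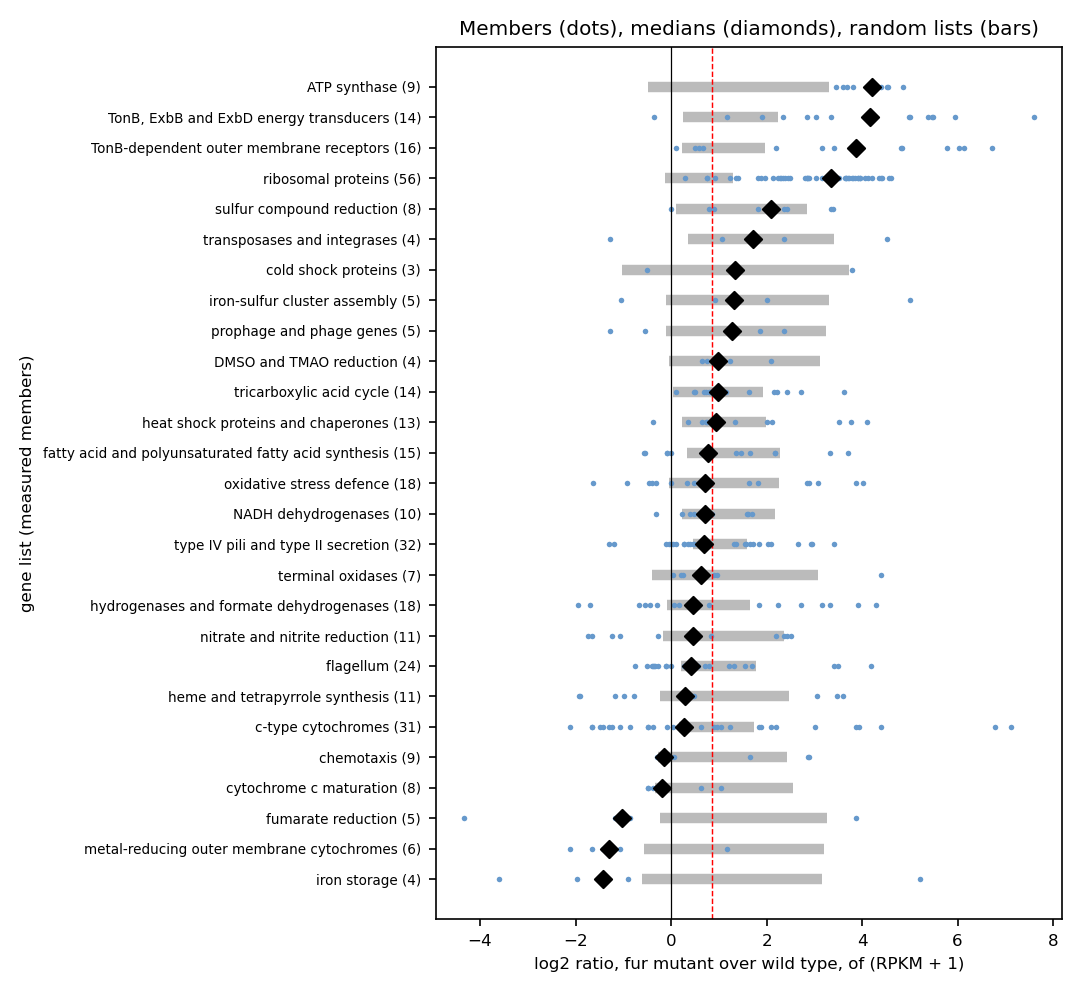
Each row is a gene list with at least 3 measured members (number in parentheses), with the log2 ratio of mutant over wild type RPKM plus 1 on the horizontal axis, dots for members, a diamond for the median, a grey bar for the middle 95% of 10000 expression-matched random lists and the dashed red line at the median of all genes, 0.86. The medians of 4 lists lie above their bars and of 3 below, and the other 20 lie inside. All 7 of those outside also lie outside the middle 95% on recovered reads, which cover 3 of 6 genes of the metal-reducing list.

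The other lists lay inside the range of their random lists. Sulfur compound reduction had 5 of 8 genes higher and 0 lower (median 2.09, percentile 90.1), led by polysulfide reductase subunit B, swp_1239 (64.3 and 683 RPKM, interval 8.68 to 13.2), and adenylylsulfate kinase, swp_1592 (2.20 and 31.6 RPKM, interval 5.27 to 54.8). Without 1 accidental match, 4 of 7 were higher (median 1.82, percentile 82.1). The tricarboxylic acid cycle had 7 of 14 genes higher and 0 lower (0.98, percentile 77.5), led by the 2-oxoglutarate dehydrogenase gene swp_2949 (6.77 and 94.2 RPKM, interval 10.5 to 18.7) and the succinate dehydrogenase gene swp_2950 (31.5 and 213 RPKM). Its 1 accidental match left out, 7 of 13 were higher (1.14, percentile 82.4). DMSO and TMAO reduction had 2 of 4 genes higher (0.99, percentile 52.6). The 2 higher genes, swp_2773 and swp_2772, lie in the run of the higher nitrate reductase genes. Of these 2, swp_2773 is listed 2 times, with a log2 ratio of 2.09 by the first entry and 0.79, not past 2-fold, by the second. Its entries have equal wild type values, and their mutant values differ by the factor of 2.47 between scales. Heat shock proteins and chaperones had 6 of 13 higher (0.93, percentile 76.8). Among these chaperones, GroES, swp_0584, had 3.65 and 78.3 RPKM (interval 6.97 to 107), and heat shock protein 90, swp_1732, had 19.4 and 233 RPKM. Chemotaxis had 3 of 9 higher (-0.16, percentile 6.21), with a median of 1.13 on recovered reads, below that of all genes and at percentile 4.39.

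Terminal oxidases had 1 of 7 genes higher (median 0.62, percentile 49.5), NADH dehydrogenases 3 of 10 (0.70, percentile 39.5), the flagellum 7 of 24 (0.41, percentile 12.4), and fatty acid synthesis 7 of 15 (0.78, percentile 38.6), each with 0 lower. For terminal oxidases without 1 accidental match, 1 of 6 was higher (0.43, percentile 30.5). Type IV pili and type II secretion had 13 of 32 higher and 2 lower (0.69, percentile 28.4). In fatty acid synthesis the largest ratios were those of PfaA, swp_3550 (3.04 and 51.9 RPKM, interval 13.4 to 22.1), and PfaD, swp_3554 (8.91 and 98.2 RPKM, interval 7.98 to 15.6), which build the omega-3 fatty acids of cold-water bacteria. The 3 cold shock genes (2 higher; 1.33, percentile 70.9), the 5 phage genes (3 higher and 1 lower; 1.27, percentile 61.5, with 3 accidental matches) and the 4 transposases and integrases (3 higher and 1 lower; 1.72, also percentile 61.5) had medians above 0. Without the accidental matches 2 phage genes are left, too few to place as a group. Of these lists, the cold shock gene swp_1075 had 51.5 and 728 RPKM, and the phage integrase swp_4482 had 83.8 and 33.9 RPKM, 1.98- to 3.11-fold lower.

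Genes past 2-fold often lay side by side. There were 83 runs of at least 3 neighbours on 1 strand in 1 direction, 79 higher and 4 lower, with 351 genes in all, against a mean of 37.5 runs in 1000 shuffles of the ratios (central 95% range 28 to 48). The longest run had 18 genes and was led by ribosomal protein S17, swp_2020 (2096008 to 2096256, plus strand; log2 ratio 1.96, off the common scale). The next had 13 genes and was led by elongation factor Tu, swp_1995 (2072970 to 2074154; 7.47 and 197 RPKM), whose value is uncertain because the last gene of the run, swp_2008, is annotated as the same protein with the same coding length of 1185 bases and could share its reads. The run of 12 genes from the outer membrane receptor swp_4957 (5183854 to 5186292, minus strand; 9.29 and 508 RPKM, interval 42.7 to 71.2) to swp_4945 had a median log2 ratio of 5.56. A run of 7 genes from swp_3979 to swp_3985, singled out after its values were seen, had a median of 5.73 and holds TonB, ExbB, ExbD and the hemin importer. The 4 lower runs were those of the fumarate reductase genes from swp_0429, the cytochrome and MtrB genes from swp_3278, the nitrate reductase genes from swp_4456, and a run of 3 genes around the acetyltransferase swp_0118. In all, 11 runs held ribosomal protein or ATP synthase genes.

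**Figure D4:**
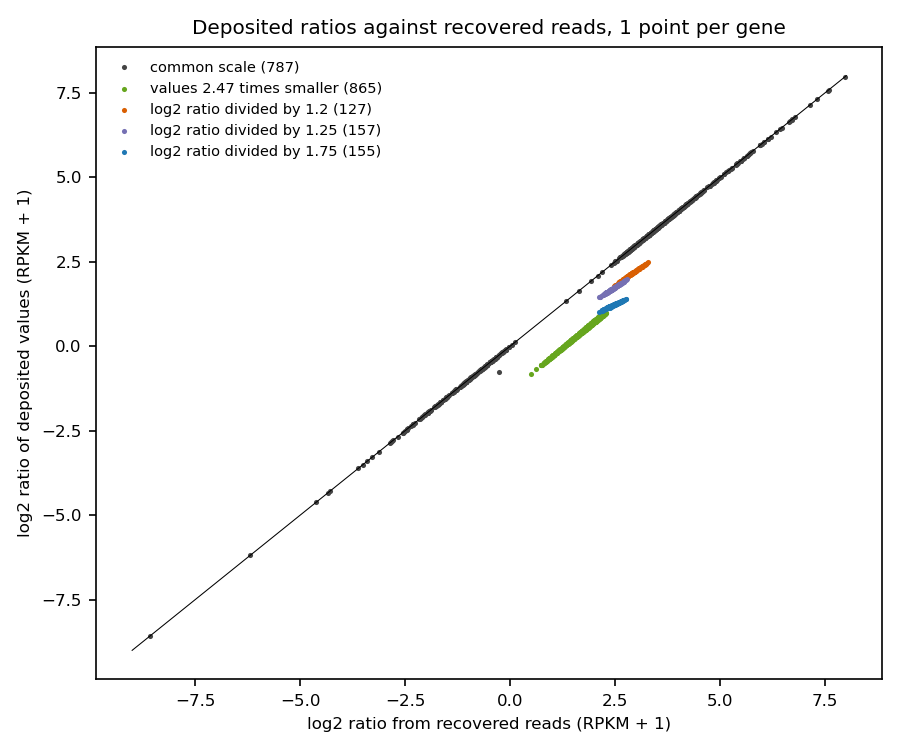
Each point is a gene with recovered reads, with the log2 ratio of mutant over wild type from recovered reads on the horizontal axis, the log2 ratio of the deposited RPKM on the vertical axis, each of values plus 1, colours for the scale that its mutant value follows, and a line where both ratios are equal. Genes on the common scale lie on the line, except 1 point for a gene listed 2 times, and those on the other scales lie below it. Of these, 865 have values 2.47 times smaller, and the rest have log2 ratios, of values 1.24 times smaller, divided by 1.2, 1.25 or 1.75.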

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

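The tests of the first pattern were chosen after its values were seen, as was the test of divided ratios in the second; the length test was fixed before its value was computed, though single genes had been seen. The listed genes do not account for all reads in either library: 66.7% of the wild type reads (exact binomial 95% interval 66.6 to 66.7) and 44.0% of the mutant reads (43.9 to 44.1) are the difference between the total that the step of the values gives and the sum over the listed genes. Where these reads fall was not analysed here. The mutant share of 44.0% would be larger with a mutant total 1.24 times larger, which its interval does not cover.

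Most listed genes have higher values in the mutant library, with a median log2 ratio of 0.86 as deposited and 88.4% of the genes past 2-fold higher. The wild type library is richer in a few transcripts, as its 3 most abundant genes hold 16.7% of its reads against 4.31% in the mutant library, but leaving them out of the totals left the median of recovered reads at 1.95 (95% interval 1.91 to 2.0), which argues against them as the whole cause. The scales that the mutant values follow do not account for it either, since the reads put on 1 scale have a higher median still, 2.14 (2.10 to 2.19). Both medians of recovered reads would be about 0.305 lower with a mutant total 1.24 times larger. A smaller share of mutant reads outside the listed genes, 44.0% against 66.7%, remains a candidate explanation that cannot be told apart from a general difference, because that share follows from the listed genes' own sum. The missing regulator also stays open as a biological explanation, untested, since each genotype is 1 library.

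Mutant values follow several scales. The 444 values in the combined table that are off the common scale and above a wild type value over 0 were tested on a step 1.24 times smaller. Of these, 98.9% give whole reads when their log2 ratio is multiplied by 1.2, 1.25 or 1.75, while any other single divisor between 1.05 and 2.5 gave at most 5.41%. Log2 ratios divided by one of these numbers before the values were written are consistent with that, and a gene length 3 bases shorter or longer than the coding length is not, as it gave whole reads for 0.225%. For the pair of genes swp_2773 and swp_3271, the entries listed 2 times differ by the same factor of 2.47 in the mutant library (156 and 63.3 RPKM, 490 and 198 RPKM), with equal wild type values. The other gene listed 2 times, swp_0402, does not follow this factor. Its entries had 206 and 210 RPKM in the wild type and 120 and 174 RPKM in the mutant library. No biological explanation of the scales was tested.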

How the results depend on the processing

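The alternatives based on recovered reads, other gaps or scalings for runs, lists without accidental matches and lists by product name alone were chosen after seeing the data, the others were planned. The counts depend on the scaling: lower genes were 416 after TMM and 361 after median-of-ratios scaling. Higher genes were 1788 for recovered reads scaled to the library total, 1714 without the 3 most abundant genes, and higher and lower genes 404 and 356 after median-of-ratios scaling of recovered reads. The counts of 1788 and 1714, and those from counting intervals, rest on the mutant total of the common scale. All 404 higher genes, and 122 of the lower ones, were also called on the deposited values. A minimum of 50 RPKM left 600 higher genes of fewer tested, a 4-fold threshold 654 higher and 38 lower, and counting intervals wholly past 2-fold 1595 and 71. Runs were 200 with at least 2 genes and 177 for recovered reads. The authors' log2 ratio, in the authors' deposited table, gave 988 higher and 172 lower. The deposited values follow scales that differ between genes inside and outside that table, so this is no separate check of the counts. List medians under TMM scaling were 3.22 for ATP synthase, 2.36 ribosomal proteins, -2.29 metal-reducing cytochromes, 0.0398 DMSO and TMAO, 0.0088 tricarboxylic acid cycle, -0.0464 heat shock, -0.16 fatty acids, -0.24 NADH dehydrogenases, -0.27 pili, -0.36 terminal oxidases, -0.51 hydrogenases, -0.55 flagellum, -0.66 c-type cytochromes, -1.13 chemotaxis and -1.16 cytochrome maturation. Under median-of-ratios scaling they were 3.34 for ATP synthase, 2.48 ribosomal proteins, -2.18 metal-reducing cytochromes, 0.15 DMSO and TMAO, 0.13 tricarboxylic acid cycle, 0.0716 heat shock, -0.13 NADH dehydrogenases, -0.15 pili, -0.24 terminal oxidases, -0.43 flagellum, -0.55 c-type cytochromes, -1.01 chemotaxis and -1.04 cytochrome maturation. For recovered reads with that scaling they were 2.03 for ATP synthase, 1.17 ribosomal proteins, -3.23 metal-reducing cytochromes, -0.0701 DMSO and TMAO, 0.0605 tricarboxylic acid cycle, 0.0673 heat shock, -0.13 NADH dehydrogenases, -0.12 pili, -0.25 terminal oxidases, -0.44 flagellum, -1.01 chemotaxis and -0.74 cytochrome maturation. For recovered reads scaled to the library total they were 2.12 for c-type cytochromes, 1.42 cytochrome maturation, 1.98 NADH dehydrogenases, 1.69 flagellum, 2.54 phage genes and 1.98 pili, and without the 3 most abundant genes 1.94, 1.22, 1.79, 1.5 and 1.80 for these without the phage genes. In the authors' deposited table, which holds only genes past 2-fold, the log2 ratio gave 1.64 for NADH dehydrogenases, 1.73 flagellum, 2.21 fatty acids and 1.73 pili. Of the named genes past 2-fold 2 took the other sign, swp_2773 at -0.0619 and swp_3271 at -0.24 for recovered reads with median-of-ratios scaling, while some named genes within 2-fold also took the other sign under centring scalings. The sizes are less stable: 131 of 152 named genes counted as moved under TMM scaling and 129 under median-of-ratios scaling. For recovered reads with median-of-ratios scaling, which lowers log2 ratios by up to 2.18, 138 of 144 did. Apart from the restricted tables, the cause was not tested. The pseudocounts, no minimum, means over members and removal of accidental matches left every list median inside its interval. For short lists such as iron storage (-3.61 to 5.21) this interval runs from the smallest to the largest member. A mean, or a median of fewer members, cannot leave it, so there it is no test. The iron storage mean was -0.31 against a median of -1.43, and the nitrate median went from 0.46 to -0.27 without accidental matches. Of the 152 named genes, 87 counted as moved with a pseudocount of 10 and 3 with 0.5. No paired analysis was possible because each genotype is 1 library. The planned Fur site alternatives were not run, without a genome sequence. Depth limits low genes most, as the median wild type gene has 65 reads.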

Other observations

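The gene groups here were put together after the values were seen, as was the choice of the abundant genes; the length and growth tests were fixed before their values were computed, though single genes had been seen. Universal stress proteins, which accumulate when growth slows, were lower in the mutant library: of 5 genes, 4 were lower and 1 neither, with a median log2 ratio of -1.97, -2.83 from that of all genes, at percentile 0.02 among random lists, and -4.11 from it at percentile 0.005 on recovered reads. Besides swp_4459, these were swp_1057 (1098 and 220 RPKM, 4.35- to 5.75-fold lower), swp_1055 (3444 and 879 RPKM, 3.65- to 4.21-fold lower) and UspE, swp_2581 (853 and 324 RPKM, 2.42- to 2.87-fold lower). Genes named for efflux had 14 of 17 genes higher, 1 lower and 2 neither, with a median of 2.85 at percentile 99.0, 1.99 above all genes as deposited. On recovered reads they were 0.71 above all genes, at percentile 95, inside the range of random lists. Of the 17, 6 are named for metals, cations or potassium and not for drugs, and without these 10 of 11 were higher and 0 lower (median 2.89, at the upper edge of the range of random lists as deposited, percentile 97.48, and inside it at percentile 94.2 on recovered reads). The pump genes swp_3156 (4.41 and 335 RPKM, interval 55.7 to 107) and swp_3155 (6.72 and 327 RPKM, interval 30.5 to 82.4) lie side by side, and swp_2309 had 7.27 and 420 RPKM (interval 45.0 to 75.3). GGDEF and EAL domain proteins, which make and break the signal cyclic di-GMP, had 4 of 17 higher and 1 lower (median 0.48, percentile 3.38, and -0.38 from that of all genes). Peptidases had 34 of 72 higher and 0 lower (0.90, percentile 49.9), and amino acid and purine synthesis 11 of 18 higher and 0 lower (1.48, percentile 81.2).

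The most abundant listed transcript was that of a ribosomal subunit interface protein, swp_3757, a protein type that holds ribosomes in a resting state. It had 272045 RPKM in the wild type and 95069 RPKM in the mutant library, or 9.88% of the wild type reads (exact binomial 95% interval 9.84 to 9.91) and 3.45% of the mutant reads (3.43 to 3.47). The hypothetical proteins swp_4012 (114019 and 12989 RPKM, 8.64- to 8.92-fold lower) and swp_4510 (58913 and 10697 RPKM, 5.35- to 5.67-fold lower) came next. Initiation factor 3, swp_2463, had 10192 and 23192 RPKM, with the mutant value off the common scale.

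Ribosomal protein and ATP synthase genes stand above the other genes, and a hypothesis is that the cultures differed in growth state. Gene length bias is argued against, since the ribosomal protein median of 3.37, over the 54 genes left without accidental matches, stayed at percentile 100 among random lists matched on coding length (middle 95% of these lists 0.48 to 1.71), and that of ATP synthase did too. Other growth machinery, made of tRNA ligases, translation factors and RNA polymerase, had 26 of 38 genes higher, 2 lower and 10 neither, with a median of 2.09 at percentile 99.95, 1.23 above all genes. On recovered reads it was 0.65 above all genes, at percentile 99.98. Of the 38 genes, 9 share a cluster with ribosomal protein or ATP synthase genes, and without them, a choice made after the values were seen, 18 of 29 were higher and 2 lower, with a median of 1.91 at percentile 99.8. These percentiles, above the middle 95% of random lists as set beforehand for the whole list, are consistent with a difference in growth state. Among the 29 are release factor 2, swp_4304 (log2 ratio 3.52), and prolyl-tRNA synthetase, swp_3484 (3.33). Genotype and culture cannot be separated with 1 library each, so an effect of the missing regulator on growth, or on these genes directly, stays open and untested.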
